A study of Zea mays with 46 samples.

How the data were processed

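The series describes 46 samples: DAP-seq with tagged maize factors, ChIP-seq with a P1 antibody, and RNA-seq of 9 samples with 3 libraries each. DAP-seq DNA came from leaves of hybrid seedlings 2 weeks old, and protoplasts came from seedlings 12 days old. RNA-seq and most ChIP-seq and DAP-seq reads were single reads of 50 nt, per the labels' protocols. A few DAP-seq samples had reads of 150 nt. Reads were split with bcl2fastq 2.20.0, checked with FastQC, trimmed with Trimmomatic and aligned to B73 RefGen_v4, for which Bowtie2 2.3.4.1 and HISAT2 2.0.4 are listed, per the submitters' processing notes. The counting tool, its handling of strand and of reads with several places, the annotation, the peak caller, its threshold and how replicates entered a peak call are not given in the sources used here.

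The RNA-seq file holds raw read counts per gene and library as deposited, with no normalization, for 39005 genes and 27 libraries. Gene copies that share reads, and genes that overlap on opposite strands, are therefore uncertain. The peak files hold the position of each peak, and 2 of them (GBP20 and MYB40) also hold a deposited score per peak, whose scale is not given. Peak lists were used for 14 DAP-seq samples, 11 with demethylated DNA and 3 with methylated DNA (GBP20, HSF24 and MYB40), and for 2 ChIP-seq samples. The other factors and the tag-only and genomic DNA samples of the series were not analysed here.

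Some labels disagree. The titles of the protoplast ChIP-seq samples contradict their treatment fields, and samples were grouped by treatment, which puts the peak list with the antibody sample. The growth text names other hybrids than the sample fields, which give B73 x A632 and were used. P1-rr and P1-ww carry the same inbred name, A619, in the labels. The pericarp samples are called kernels in their tissue field. The silk ChIP-seq list was called against P1-ww material. The only P1-ww silk ChIP-seq sample in the labels is an input, but whether the control was input or immunoprecipitate is not stated, and an F1 signal absent from P1-ww material need not come from P1 alone.

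Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter, a quasi-likelihood fit with 1 mean per group, two-sided tests, and Benjamini-Hochberg adjusted p under 0.05. Protoplasts and pericarp were each fitted alone, the 5 silk groups together because they share a tissue and season, and the difference of the P1-rr effect between tissues on the 12 P1-rr and P1-ww libraries. The F1 hybrid was compared with each parent and with the mean of the parents on the log scale. Tests, comparisons, gene lists and alternatives were fixed before the data were examined, except those that the closing section names as chosen later. Standard errors come from the fold change and its F statistic. A fold against a group without counts is a lower bound at a floor of 3 counts over the group, which is 0.0249 to 0.0493 CPM. Floors and intervals cover counting error only.

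Library totals ran from 18910941 to 54466743 counts. Libraries of 1 group differed far beyond sampling noise, with a chi-square per degree of freedom of 7.4 to 666 between pairs, so the spread between replicates sets the precision. TMM factors of the protoplast libraries ran from 0.685 to 0.989. In protoplasts, deviations from the group means correlated between libraries with the same number (r across genes 0.61, 0.67 and 0.83) and at most by 0.29 between others, so the numbers pair these libraries and blocked values stand beside the protoplast results. This pairing comes from the data, not from the labels. The other groups share numbers only.

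The fits were tested on simulated counts drawn from the real means and library sizes, with 200 changed genes per comparison. Of 50 genes changed 4-fold the test recovered 8% in protoplasts, 86% for P1 in silk, 82% in pericarp, 80% for the difference between tissues, 90% between the parents, and 92%, 90% and 92% for F1 against B73, A632 and their mean. Of genes changed 32-fold it recovered 86% in protoplasts and 98% or more elsewhere. A fold change of 4 was thus mostly missed in protoplasts without the block. In a further simulation with paired protoplast libraries, added after the data were seen, the test with the replicate block recovered 18% of 2-fold, 90% of 4-fold and 98% of 32-fold changes, with 10 false calls among 163. Without the block it recovered 0%, 0% and 44%. Both simulations changed only genes above a minimum expected count per library, so they do not give the recovery of low-count genes.

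Gene sets were tested with limma 3.58.1 on voom values: camera with a preset correlation of 0.01, camera with an estimated correlation, and fry. Set medians were placed among 10000 random lists matched on expression. Overlaps used Fisher's exact test. Alternatives were DESeq2 size factors in edgeR, no filter, the Wald test of DESeq2 1.42.0, a change of 2-fold or more, the replicate number as a block, other libraries in the fit, and each library left out.

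Peaks were compared with Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. A peak meets another with 1 bp or more in common. The expected share came from 100 shuffles within chromosomes (20 for lists other than those of P1) and from 100 shifts of up to 500 kb, with the span of each chromosome taken from the last peak end. On 2000 simulated intervals with 600 planted overlaps the method found 605, with 7.88 after shuffling. Wilson intervals have a level of 95%. Coordinates are 1-based on B73 RefGen_v4. Figures were drawn with matplotlib 3.10.9.

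The rule for named genes asked for P1, members of the pigment pathway and the genes with the widest change that have a product name. The reference table belongs to the NAM-5.0 assembly and none of its entries matched the identifiers of the count table, so names could not be given. The rule was kept without its name condition: adjusted p under 0.05, a mean of 5 CPM or more in a group, all libraries of one group above those of the other (not asked for the difference between tissues), and the 2 widest changes per direction. The fixed gene lists, the level of P1 itself as a check of the labels, the share of P1-bound genes and the DAP-seq peaks at p1 were not run for the same reason.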

Results

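The series followed P1, a maize MYB transcription factor that switches on flavonoid genes in silk and pericarp and so gives red phlobaphene pigments and maysin-type compounds. RNA-seq counts covered 9 groups of 3 libraries each, 27 in all. Silks at 0 days after pollination came from the inbreds B73 and A632, from their F1 hybrid, and from the P1-rr and P1-ww stocks. P1-rr is an allele with red pericarp and cob, and P1-ww gives colourless ones. Pericarp at 14 days after pollination came from P1-rr and P1-ww, and leaf protoplasts (plant cells freed of their walls) of the F1 hybrid carried either P1 behind the strong 35S promoter (35S:P1) or an empty vector. Library totals ran from 18910941 to 54466743 counts over 39005 genes, and the 6 pericarp libraries were among the shallowest, with 18910941 to 25175345. DNA binding was described by 16 peak lists. Of these, 14 came from DAP-seq, in which a tagged factor made in the test tube picks fragments out of naked genomic DNA, and 2 from ChIP-seq with a P1 antibody in protoplasts and in F1 silk. The reference table held none of the gene identifiers of the count table, so genes are given by identifier alone and known P1 targets were not looked up. For each comparison at most 2 identifiers per direction are named, and each printed level is a mean in CPM (counts scaled to the size of the library) ± SD of 3 libraries.

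The first question was which genes change when P1 is put into leaf cells. In protoplasts, 35S:P1 raised 35 of 25127 tested genes and lowered 0 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median absolute log2 change among the 35 was 6.30. This test mostly missed simulated changes of 4-fold or less, so that value is no measure of a typical rise with P1. Zm00001d007403 stood at 2101 ± 2043 CPM with 35S:P1 and 1.37 ± 0.405 with the empty vector (log2 change 10.30 ± 1.28 SE, edgeR adjusted p = 0.0457). Zm00001d047252 stood at 557 ± 388 against 0.396 ± 0.0603 CPM (log2 change 10.19 ± 0.87 SE, edgeR adjusted p = 0.0235). Both genes were lowest in 35S:P1 replicate 2, at 242.5 and 165 CPM, which was still far above every empty-vector library. At an unadjusted p under 0.05 edgeR gave 1616 genes, of which 216 were lower, and DESeq2 called 657, of which 16 were lower. Libraries with the same replicate number varied together, and with that number as a block edgeR called 1305 higher and 272 lower genes, all 35 among them. With the block the adjusted p was 0.000621 for Zm00001d007403 and 5.79e-05 for Zm00001d047252. Without the block the 35 calls, though not the size of the rises, depended on which library was left out, for a reason not tested. The test called 0 genes, the 2 named ones lost as well, without 35S:P1 replicate 1 or without empty-vector replicate 1, 2 or 3. It called 91 without 35S:P1 replicate 2 and 96 without replicate 3. Where the calls of the named genes were lost their log2 changes stayed at 10.13 to 10.61 for Zm00001d007403 and 10.03 to 10.35 for Zm00001d047252.

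**Figure D1:**
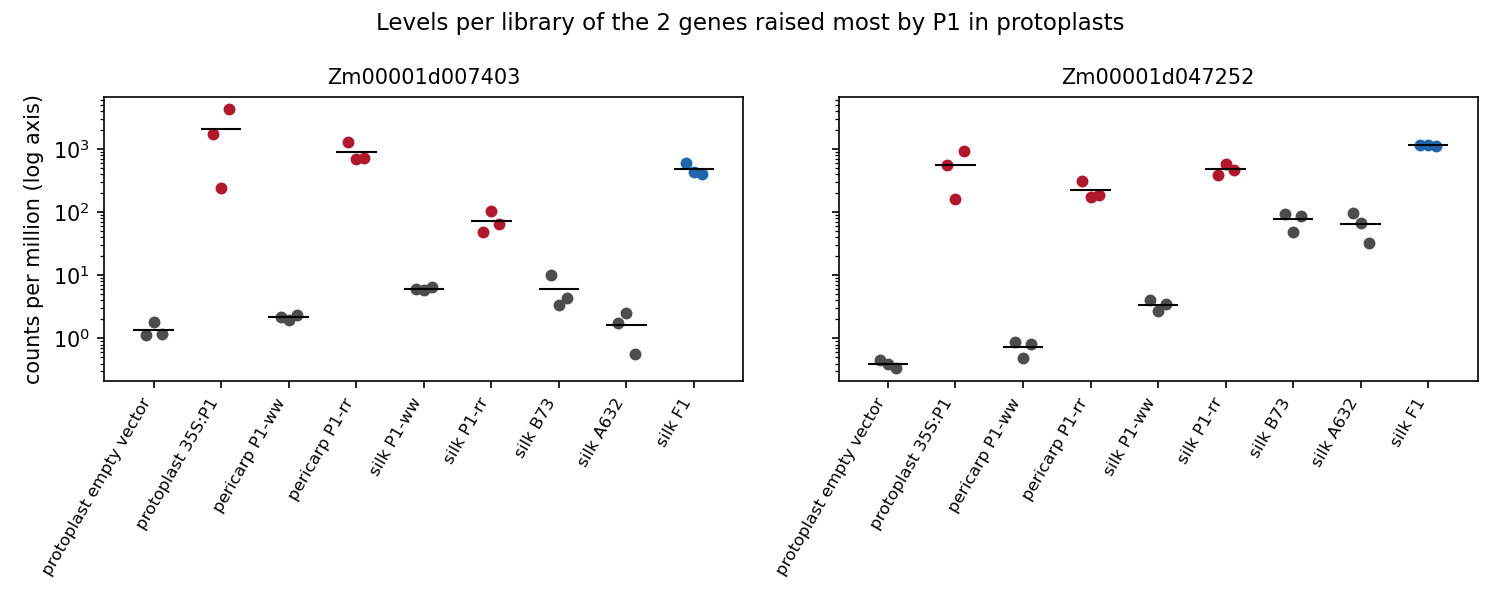
CPM on a log axis in each of the 27 libraries for the 2 genes that rose most with P1 in protoplasts. Points are libraries and bars are means of 3; red marks groups with 35S:P1 or P1-rr, blue the F1 hybrid silk and grey the others, and Zm00001d047252 reached 1162 CPM in F1 silk against 77.4 in B73 and 66.0 in A632.

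The second question was what differs in silks that carry an active or an inactive P1 allele. In silk, 1481 of 25250 genes were higher and 1659 lower in P1-rr than in P1-ww, a total of 3140 (edgeR, adjusted p under 0.05). Most changes were modest, with a median absolute log2 change of 0.81 among the called genes and 595 higher and 637 lower by 2-fold or more. The widest contrasts were between presence and absence. Zm00001d029242 stood at 5.60 ± 0.785 CPM in P1-rr and had no count in P1-ww, a rise of at least 125-fold against a floor of 3 counts over the group. Zm00001d029205 stood at 5.32 ± 0.414 CPM in P1-rr against no count, at least 118-fold higher. Zm00001d036825 fell from 18.0 ± 1.83 CPM in P1-ww to 0.0373 ± 0.0356 in P1-rr (log2 change -8.80 ± 0.40 SE, edgeR adjusted p = 1e-08). Zm00001d021845 fell from 7.08 CPM (5.29 to 9.18 in the 3 libraries) to 0.0392 ± 0.0412 (log2 change -7.45 ± 0.42 SE, edgeR adjusted p = 1.02e-07). None of these 4 was called in protoplasts, with or without the replicate block, and there Zm00001d029205 stood at 3.44 ± 0.530 CPM with 35S:P1 and 4.20 ± 1.43 with the empty vector. Empty-vector protoplasts also held Zm00001d029242 at 1.99 ± 1.08 CPM, Zm00001d036825 at 2.57 ± 1.245 and Zm00001d021845 at 2.62 ± 0.790. Mean levels in B73 and A632 silk were 1.90 and 2.61 CPM for Zm00001d029242 and 5.91 and 7.33 for Zm00001d029205. For Zm00001d021845 they were 13.1 and 2.76, and for Zm00001d036825 20.3 and 0.0601. All 4 were thus read in leaf cells without 35S:P1, and their rise or fall need not come from P1. The count of changed genes was 1814 without P1-rr replicate 1, 1449 without P1-rr replicate 2, 1657 without P1-ww replicate 2 and 2061 without P1-ww replicate 3. A fit on the 6 compared libraries alone called 4982 genes.

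In pericarp, the tissue in which P1-rr gives the red kernel, 1267 of 22209 genes were higher and 1611 lower than in P1-ww, a total of 2878 (edgeR, adjusted p under 0.05). At 2-fold or more there were 595 higher and 1006 lower genes. Zm00001d003046 rose from 1.21 ± 0.514 CPM in P1-ww to 1054 ± 307 in P1-rr (log2 change 9.71 ± 0.45 SE, edgeR adjusted p = 6.2e-05). It also stood higher in P1-rr silk, at 38.4 ± 28.0 against 1.18 ± 0.168 CPM. Zm00001d036615 stood at 6.82 ± 0.360 CPM in P1-rr pericarp and had no count in P1-ww, at least 139-fold higher (edgeR adjusted p = 0.000831). This gene had no count in P1-ww silk either, but stood at 23.2 ± 4.21 CPM in empty-vector protoplasts and 20.3 ± 7.38 in B73 silk. The genes that fell most were the same 2 as in silk: Zm00001d036825 fell by 9.34 ± 0.49 SE (edgeR adjusted p = 0.000103) and Zm00001d021845 fell by 8.77 ± 0.55 SE on the log2 scale (edgeR adjusted p = 0.00026). Single libraries moved the count: it was 890 without P1-rr replicate 2, 1541 without P1-rr replicate 3, and 1122, 1196 and 839 without P1-ww replicate 1, 2 and 3. DESeq2 called 4713 genes, a fit on all 27 libraries 1400, and a fit with the replicate number as a block 1129, of which 396 were higher and 733 lower.

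The P1-rr effect was then compared between the tissues by the interaction term of a fit on the 12 P1-rr and P1-ww libraries. It differed for 2902 of 24364 genes, with 1497 more positive in pericarp and 1405 more positive in silk (edgeR, adjusted p under 0.05). Zm00001d029195 was the clearest gene on the silk side. It stood at 333 ± 32.8 CPM in P1-rr silk against 1.85 ± 0.0821 in P1-ww silk, while pericarp had 0.448 ± 0.0440 and 0.477 ± 0.125 CPM (log2 difference -7.60 ± 0.35 SE, edgeR adjusted p = 2.03e-07). Zm00001d007403, one of the 2 protoplast genes, rose in both tissues but more in pericarp, from 2.16 ± 0.201 to 913 ± 348 CPM, against 6.18 ± 0.357 to 73.6 ± 29.0 in silk (log2 difference 5.16 ± 0.46 SE, edgeR adjusted p = 9.06e-05). Zm00001d029062 stood at 5.53 ± 3.98 CPM in P1-ww pericarp and at or below 0.192 in the other 3 groups (log2 difference -7.39 ± 1.73 SE, edgeR adjusted p = 0.0177), a call that was lost without silk P1-rr replicate 1 or 2. Zm00001d052759 had a difference of 5.27 ± 1.34 SE (edgeR adjusted p = 0.0252). Much of it rested on P1-rr pericarp replicate 2, with 27.2 CPM against 0.952 and 1.67 in the other replicates; without that library the difference was 2.34, still called, since silk had 1.15 ± 0.372 CPM in P1-rr and 3.86 ± 0.720 in P1-ww. The call was lost in 9 of 17 alternatives, among them the replicate block (adjusted p = 0.0529) and DESeq2. The count was 1545 without silk P1-rr replicate 1, 1651 without P1-rr replicate 2, and 1859, 1627 and 1718 without silk P1-ww replicate 1, 2 and 3. A fit on all 27 libraries called 240 genes, 236 of them among the 2902. Of the 10 genes named for P1-rr against P1-ww or for the difference between tissues, 7 lie among identifiers where genes changed alike in both tissues gather, all but Zm00001d021845, Zm00001d052759 and Zm00001d007403. These identifiers were picked after the data were seen, for a share of 10% or more of such genes, and 4 of the 7 are such genes themselves. With each gene left out of its own share all 7 remained. Zm00001d029242, Zm00001d029205, Zm00001d029195 and Zm00001d029062 lie in a single stretch of identifiers, 28500 to 29399, with 13.5% of tested genes changed alike. Over 9 windows of 100 numbers in a row, 1000 permutations gave at most 6.99%. The window of Zm00001d036615 had 23.1%, against at most 20.8% in permutations. Those of Zm00001d036825 and Zm00001d003046 had shares within reach of permutations. None of this gives a source for the change of any 1 gene, and a difference in nearby DNA between the stocks was not tested for any of them.

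The genes that the 3 P1 comparisons have in common were counted next. These comparisons share no libraries, but silk and pericarp share the P1-rr and P1-ww stocks. Any other DNA difference between those stocks could make genes change alike in both tissues, so that overlap does not measure P1 alone. Of the 29 protoplast-raised genes that were also tested in silk, 17 were higher in P1-rr silk, where 1.75 would be shared by independent lists (Fisher's exact test, two-sided, p = 4.58e-14, Benjamini-Hochberg adjusted 1.63e-13 over 32 overlaps). In pericarp 16 of 27 were higher, against 1.59 for independent lists (Fisher's exact test p = 1.37e-13, adjusted 4.38e-13). A core of 14 genes rose in protoplasts, silk and pericarp. Zm00001d047252 belonged to it, with 483 ± 97.9 against 3.43 ± 0.684 CPM in silk and 227 ± 78.4 against 0.724 ± 0.210 in pericarp. Between silk and pericarp 222 genes were higher and 220 lower in both, against 75.6 and 99.2 for independent lists, while 66 and 49 went in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 changes was 0.15 between protoplast and silk, 0.11 between protoplast and pericarp and 0.37 between silk and pericarp, and Spearman's rho 0.11, 0.03 and 0.18. With the replicate block in protoplasts 144 genes were higher in protoplasts and silk (67.1 for independent lists) and 40 were lower in both (15.7), and 125 and 29 genes were shared with pericarp (58.3 and 16.1). In opposite directions, 92 genes were higher in blocked protoplasts and lower in silk (76.1 for independent lists) and 6 lower and then higher (13.85). With pericarp these were 90 (72.2, Fisher's exact test p = 0.0283, adjusted 0.0566) and 11 (13.0).

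The 35 protoplast genes were next followed as a set, which was defined after the data were examined. In silk their log2 change with P1-rr had a median of 2.00, with 17 of 29 higher and 1 lower, and in pericarp a median of 3.59, with 16 of 27 higher and 2 lower. These medians cover the members that passed the filter. Without it the median was 1.31 over 35 genes in silk and 1.66 over 32 in pericarp, and with all 27 libraries in the fit 1.21 over 35 in pericarp. In the F1 hybrid silk 21 of 29 were higher and 2 lower than the mean of the parents, with a median of 2.17. Against B73 the count was 21 higher and 2 lower, and against A632 20 higher and 2 lower, while between the parents 8 were higher in B73 and 7 in A632. In 1 of the 29 genes a B73, A632 or F1 group had no count, and with its floor in place the F1 median stayed at 2.17. The median level over the 35 genes was 19.6 ± 2.15 CPM in F1 silk, 5.77 ± 2.12 in B73 and 5.98 ± 1.21 in A632, 4.54 ± 0.340 in P1-rr and 1.72 ± 0.171 in P1-ww silk, and 90.0 ± 41.2 in 35S:P1 and 0.861 ± 0.150 in empty-vector protoplasts. By an exact two-sided permutation test of the 3 F1 against the 6 parent libraries the set's level differed with p = 0.0119, the smallest of 84 splits, and every F1 library lay above every parent library. Compared with all other genes by limma's camera test with a preset correlation of 0.01, p was 1.4e-16 in silk, 3.7e-13 in pericarp, 5.7e-11 for F1 over the mid-parent and 0.81 between the parents. With an estimated correlation these p values were 0.0037, 0.024, 0.014 and 0.91, and over the 28 set tests the adjusted p = 0.057 in silk and 0.12 in pericarp and F1 with an estimated correlation, so the calls did not hold there.

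**Figure D2:**
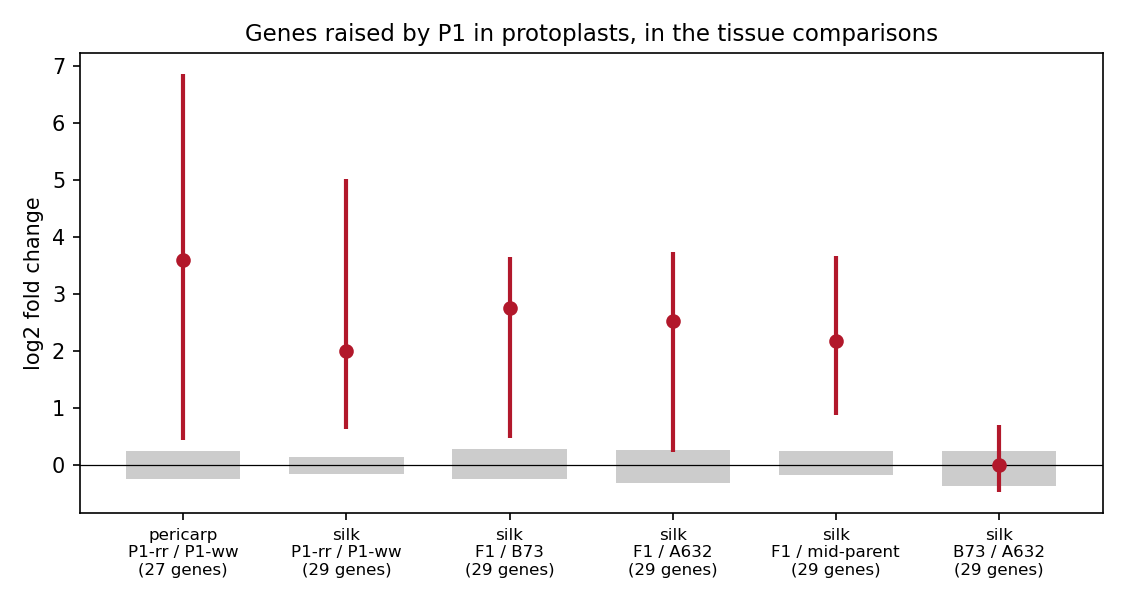
Log2 fold changes of the tested members of the 35 genes that P1 raised in protoplasts without the replicate block, in 6 tissue comparisons. Points are medians and lines run from the lower to the upper quartile of the genes; grey boxes hold 95% of the medians of 10000 random lists of the same size and expression, and the median lies above the box in every comparison except B73 over A632, where it is 0.00.

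The parents of the hybrid differed widely in silk: 6266 of 25250 genes were higher and 7110 lower in B73 than in A632 (edgeR, adjusted p under 0.05), and 3407 and 3316 by 2-fold or more. Some genes were read in 1 parent only. Zm00001d035570 stood at 31.1 ± 7.51 CPM in B73 and had no count in A632, at least 1038-fold higher, and Zm00001d038519 at 20.5 ± 3.92 CPM and no count, at least 676-fold higher. Zm00001d043290 had no count in B73 and stood at 17.8 ± 5.18 CPM in A632, at least 593-fold lower in B73. Zm00001d036066 had 3 counts in B73 and 105 ± 28.9 CPM in A632, a ratio of 3522 with a counting interval of 1205 to 17083. Reads were placed on the B73 genome, so a gene missing or divergent in A632 reads low there whatever its expression. A set of 134 genes had 5 or more CPM in B73 and 0.1 or less in A632, and 120 had the reverse. In F1 silk the level of the first set was a median of 0.50 times the B73 level (quartiles 0.370 to 0.618), and that of the second 0.434 times the A632 level (0.286 to 0.538).

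The hybrid was compared with each parent to ask where F1 silk goes beyond them. F1 silk was higher than B73 for 5650 and lower for 5083 genes, and higher than A632 for 6005 and lower for 5920 (edgeR, adjusted p under 0.05). Of 25250 genes, 1888 were above both parents and 1707 below both, 577 and 430 of them by 2-fold or more, and 2427 lay above 1 parent and below the other. Zm00001d037681 stood at 41.2 ± 28.6 CPM in F1 against 0.0391 ± 0.0677 in B73 and 0.273 ± 0.0872 in A632 (log2 change over the mid-parent 8.50 ± 0.53 SE, edgeR adjusted p = 1.14e-07). Zm00001d007403, the protoplast gene, stood at 483 ± 108 CPM in F1 against 6.03 ± 3.73 and 1.61 ± 0.979 (log2 change 7.23 ± 0.39 SE, edgeR adjusted p = 3.6e-08). Zm00001d041082 was lower in F1, at 0.148 ± 0.0575 CPM against 6.90 ± 1.46 in B73 and 7.95 ± 4.91 in A632 (log2 change -5.64 ± 0.51 SE, edgeR adjusted p = 3.46e-06). Zm00001d015846 lay below both as well, at 0.0364 ± 0.0415 CPM in F1, 0.346 ± 0.214 in B73 and 14.2 ± 5.96 in A632 (log2 change -5.86 ± 0.66 SE, edgeR adjusted p = 2.05e-05). Single-parent genes led the comparisons with each parent. Zm00001d043290 and Zm00001d045629 had no count in B73 and were at least 292.5-fold and 206-fold higher in F1, and Zm00001d035570 and Zm00001d020943 had none in A632 and were at least 1090-fold and 358-fold higher. Zm00001d029756 and Zm00001d050572 fell from B73 to F1, with log2 changes of -6.77 ± 0.58 SE and -6.21 ± 0.67 SE (edgeR adjusted p = 1.3e-06 and 2.32e-05). Zm00001d032064 and Zm00001d019294 each had 1 count in F1 against 12.5 ± 1.34 and 7.18 ± 4.57 CPM in A632, ratios of 1425 (255 to 56314) and 811 (145 to 32088). Against the mid-parent on the log scale 5953 genes were higher and 4319 lower, and 5432 of the higher ones were also above the arithmetic mean of the parents. Both parent comparisons use the same 3 F1 libraries, which were too few to divide: independent lists would share 1344 genes above both and 1192 below both, and part of the excess may come from the shared libraries. In 20 simulations without any effect no gene passed the adjusted p in both. At an unadjusted p under 0.05 the simulations had a median of 112.5 genes above both, against 14.5 for independent lists, and 144.5 below both, against 13.3.

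The DAP-seq lists show where each factor can bind naked DNA. P1 had 84227 peaks, between the 187162 of DOF23 and the 2196 of EREB7. The other MYB factors shared many sites with P1: 79.2% of 7328 MYB40 peaks and 52.1% of 10181 MYB100 peaks met a P1 peak by 1 bp or more, and 37.5% of P1 peaks met 1 of the 106272 MYB53 peaks, 19.2 times the share of P1 peaks shuffled within chromosomes. The shared part was larger among strong MYB40 peaks, at 87.8% (95% Wilson interval 86.6 to 89.0) of the 3006 with a score above the median and 73.3% (71.9 to 74.6) of the other 4322. Some lists lay largely within a longer list of the same family: 93.3% of MYB100 peaks met a MYB53 peak, 87.0% of 118484 DOF3 peaks met a DOF23 peak and 81.9% of EREB7 peaks met an EREB122 peak. In reverse the shares were 11.6%, 53.9% and 2.11%, which is 63.8, 25.9 and 55.8 times the shuffled share. Of MYB100 peaks, 7.465% met a peak of the shorter MYB40 list, 54.9 times the shuffled share. MYB40 was assayed on methylated and MYB100 on demethylated DNA. A short list can meet only a small share of a longer one. Lists of other families shared P1 sites too. P1 peaks met DOF23 peaks in 23.4%, CPP8 peaks in 16.9%, DOF3 peaks in 14.75%, HSF24 peaks in 14.5% and WRKY38 peaks in 11.75%. These are 6.60, 6.12, 6.71, 6.93 and 6.20 times the shuffled share, and the ratios for THX39 and NLP14 were 8.97 and 7.46. The ratios were lowest for EREB122, GBP20 and EREB7, met by 5.68%, 0.116% and 0.0332% of P1 peaks, at 2.75, 2.32 and 0.816. Each list is a single set of peaks with no replicates, so these values describe the lists, and intervals cover counting error only.

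In protoplasts with 35S:P1 the P1 antibody gave 7661 ChIP-seq peaks with a median width of 252 bp, and 68.2% of them lay in the outer 25% at either end of a chromosome. P1 DAP-seq sites were the sites they met most often. A P1 DAP-seq peak lay under 25.7% of them (95% Wilson interval 24.8 to 26.7), 13.0 times the 1.98% of shuffled peaks and 10.9 times that of peaks shifted by up to 500 kb. By ratio MYB40 (12.3) and MYB100 (11.1) followed, then WRKY38 (9.04), EREB122 (6.70) and MYB53 (6.68), and CPP8 came last with 1.29. Sites of 1 factor alone were compared for factors with 1000 or more of them. P1-only sites were met 12.96 times as often as by shifted peaks (12.05 to 13.93). WRKY38-only sites, the next, were met 7.92 times as often and CPP8-only sites 0.809 times. MYB40 and MYB100 had only 419 and 309 such sites, met by 6 and 2 peaks. Their ratios were 4.8 and 3.92 (1.075 to 14.29 for MYB100). Such sites leave out the 79.2% of MYB40 and 52.1% of MYB100 peaks that met a P1 peak. They therefore cannot set P1 apart from MYB40 or MYB100.

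In F1 silk the antibody gave 22863 peaks with a median width of 255 bp, and 55.7% lay in the outer 25% at either end of a chromosome. A P1 DAP-seq peak lay under 8.84% (95% Wilson interval 8.47 to 9.21), 4.39 times the 2.01% of shuffled peaks. DOF23 sites were met by 13.95%, CPP8 sites by 11.4% and EREB122 sites by 9.57%, and the ratios over shuffled peaks were 3.45, 3.61 and 4.04. GBP20 had the highest ratio, 6.53, with 87 peaks met. The antibody lists of the tissues had little in common: 326 protoplast peaks (4.26%) met a silk peak, 7.01 times the shuffled share, and 73 of them also met a P1 DAP-seq peak, against 3.62 for shuffled peaks. Sharing with silk brought no gain in P1 DAP-seq sites: 22.4% (95% Wilson interval 18.2 to 27.2) of the 326 met one, against 25.9% (24.9 to 26.9) of the other protoplast peaks. The site of these 73 that met most other DAP-seq lists, 7, lies on chromosome 10 from 95652192 to 95652582 of the B73 RefGen_v4 build. The next lie on chromosome 6 from 145277883 to 145278309, with 5 lists, and on chromosome 10 from 102522452 to 102522925, with 4. No annotation of that build was used here, so the genes near these sites are not named.

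**Figure D3:**
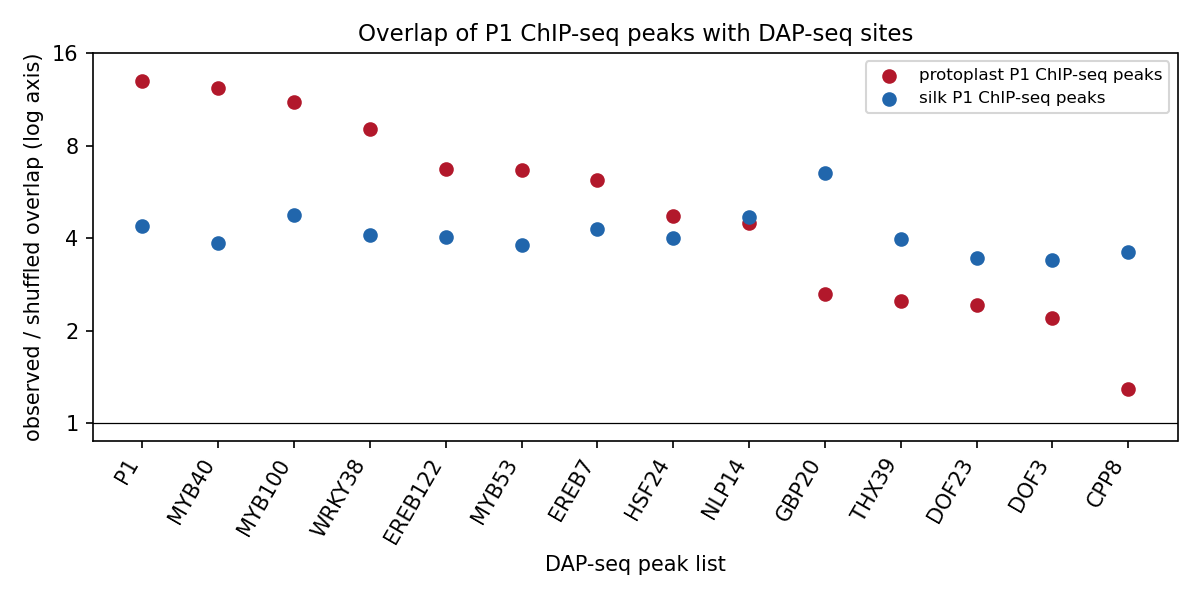
Overlap of the 2 P1 ChIP-seq lists with each of the 14 DAP-seq lists, as the share of ChIP-seq peaks that meet a site divided by the share for peaks shuffled within chromosomes (log axis). Red points are protoplast peaks and blue points F1 silk peaks; for protoplasts P1 leads with 13.0 and CPP8 is last with 1.29, and for silk the ratio for P1 is 4.39.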

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

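The split test below was chosen after its result was seen; the test of the difference between tissues was planned. The P1-rr effect differed between pericarp and silk, by the interaction test, for 2902 genes. Of 100 splits of the 12 libraries, 1, the real one, gave as many, and the highest of the others gave 1060. That other split kept the pericarp groups and mixed the silk libraries. The splits exchange P1-rr and P1-ww labels within each tissue. They therefore ask whether P1-rr has any effect, and cannot decide whether that effect differs between the tissues.

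Among the named genes Zm00001d029195 had a log2 difference of -7.60 ± 0.35 SE and rose with P1-rr in silk alone, from 1.85 ± 0.0821 to 333 ± 32.8 CPM. Zm00001d007403 had 5.16 ± 0.46 SE and was called in both tissues. Zm00001d029062 had -7.39 ± 1.73 SE and lost its call without silk P1-rr replicate 1 (-7.19) or replicate 2 (-7.08). Zm00001d052759 had 5.27 ± 1.34 SE and lost its call in 9 of 17 alternatives, among them the replicate block (4.54), the DESeq2 test (5.25) and the fits without silk P1-rr replicate 1 (5.52), 2 (5.06) or 3 (5.27), without silk P1-ww replicate 1 (5.19) or 2 (5.20) and without pericarp P1-ww replicate 1 (5.20) or 3 (5.24). Its value moved most without pericarp P1-rr replicate 2, to 2.34, with the call kept.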

How the results depend on the processing

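Chosen after the data were seen were the tests without both protoplast libraries numbered 3, the overlaps with the block in protoplasts, the set of protoplast genes and the shifts within 500 kb; the others were planned. Over the alternatives of 37 main results 75 values stayed within 1.5 times or within their spread and 51 moved. The cause was not tested except where a setting itself keeps fewer genes or libraries.

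In protoplasts the 35 genes became 117 without the filter, 657 with DESeq2, 1577 with the replicate block, 2342 with all 27 libraries in 1 model, 149 without both libraries numbered 3, and 847 without them but with the block; each of these calls held all 35. Leaving out 1 library gave 0 to 96. With the block 144 genes were higher and 40 lower in protoplasts and silk, and 125 and 29 in protoplasts and pericarp. For P1 in silk leaving out 1 library gave 1449 to 2862 genes and a fit on the compared groups only 4982. In pericarp leaving out 1 library gave 839 to 4049, DESeq2 4713, all 27 libraries 1400 and the block 1129. For the difference between tissues leaving out 1 library gave 1545 to 4195 and all 27 libraries 240. For the parents the range was 11768 to 13168, for F1 against B73 8816 to 10207, against A632 9872 to 12262 and against their mean 7677 to 11074.

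A change of 2-fold or more kept 1232 genes in silk, 1601 in pericarp, 1756 for the difference between tissues, 6723 between the parents, and 4608, 5132 and 3680 for F1 against B73, A632 and their mean. It kept 111 genes higher and 93 lower in both silk and pericarp. Without the filter the median log2 change of the protoplast genes fell to 1.31 in silk and 1.66 in pericarp, and to 1.21 in pericarp with all 27 libraries. On genes of 10 CPM or more r was 0.23 between protoplast and silk, 0.18 between protoplast and pericarp and 0.39 between silk and pericarp. When 50% of each peak had to be shared, 20.8% of protoplast and 3.48% of silk ChIP-seq peaks met a P1 DAP-seq peak, and the other 28 overlaps moved down too. The GBP20 and MYB40 lists had 1255 and 3006 peaks above their median score; lists without a score could not be reduced in this way. Which direction had more genes turned in at least 1 alternative for every comparison but protoplasts and F1 against the parental mean. With DESeq2 size factors F1 had fewer higher than lower genes against B73 (5179 and 5737) and A632 (5748 and 6303), and the difference between tissues had 1377 and 1450. Without the filter P1 in silk had 1402 higher and 1351 lower. No excess of either direction is claimed there.

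For the 30 named results 351 of 370 alternatives kept the call and 19 lost it, in 4 genes: both protoplast genes without 35S:P1 replicate 1 or any empty-vector library, Zm00001d029062 and Zm00001d052759. Only in protoplasts do the numbers pair the libraries. Elsewhere same-numbered libraries correlated by 0.10, 0.09 and 0.12 for P1 in silk and by 0.12, -0.15 and -0.14 in pericarp. The block gave 3042 genes for P1 in silk, 2517 for the difference between tissues, 13162 between the parents, and 10525, 11717 and 10047 for F1 against B73, A632 and their mean, so apart from protoplasts and pericarp it moved no count by 1.5 times. The settings foreseen for the gene lists, for P1-bound genes and for peaks at p1 were not run because no gene names or annotation of the build could be used. In protoplasts the test without the block mostly misses changes of 4-fold or less; simulated pairs with the block recovered 90% of 4-fold and 18% of 2-fold changes.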

Other observations

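All set and weighing tests in this part were chosen after the comparisons they build on were seen, and so were the splits; only the tests of P1 activity in F1 silk and of differing DNA had their outcome fixed before it was seen. Genes that P1-rr raised 2-fold or more in pericarp, without those of the protoplast set, also tended to be higher in silk: 142 of 557 were higher and 21 lower in P1-rr silk, with a median log2 change of 0.18. In F1 silk 200 of them were higher and 53 lower than the parental mean. By camera with a preset correlation p was 4.6e-10 and 0.00018; with an estimated correlation p was 0.0041 and 0.05, and 0.057 and 0.15 after adjustment over 28 tests. Genes lowered 2-fold or more in pericarp were lower in P1-rr silk in 151 and higher in 41 of 874, with p = 0.12 with an estimated correlation.

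The gene Zm00001d003046, one of the 2 named for a rise in pericarp, was low in silk of both parents of the hybrid, at 0.00978 ± 0.0169 CPM in B73 and 0.0205 ± 0.0178 in A632, and stood at 1.71 ± 0.194 in F1 silk. Among ChIP-seq peaks, those at sites of several other factors met P1 DAP-seq sites more often. In protoplasts the share was 18.7% of 3470 peaks that met no other DAP-seq list and 50% of 542 that met 3 or more. In silk it was 4.16% of 12517 and 26.7% of 1746. The DAP-seq lists overlap each other, and only 28.2% of P1 DAP-seq peaks met no other list. Peaks picked for meeting other lists would meet P1 sites more often for that reason alone. No shuffled share was computed for these classes, so nothing is concluded from the rise.

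Genes that P1 raised in protoplasts lay above both parents in F1 silk in 17 of 29, against 7.42% of 25221 other genes (odds ratio 17.7, 95% interval 7.94 to 40.6). Library scaling would move random lists too. It is argued against by the set's median log2 change over the mid-parent of 2.17 with TMM factors. In that fit 95% of random lists lie between -0.18 and 0.25. DESeq2 size factors gave 2.13, but they moved the median of all genes only from 0.034 to 0.000, so this setting adds little. Reads placed better on one parent's alleles would leave F1 between the parents. The lowest F1 library over the highest parental library had a median log2 ratio of 1.55 over the 29 genes and lay above 0 in 17. More P1 activity in F1 silk is a candidate explanation: all 17 members that P1-rr raised in silk lay above both parents and 0 of the 12 others did (Fisher's exact test p = 1.9e-08), and outside the set the share was 26.1% of 1464 genes raised by P1-rr in silk against 6.27% of the rest. Genes lowered by P1-rr in silk lay below both parents in 415 of 1659 cases against 5.48% of the rest, so F1 and P1-rr silks share part of their difference from their controls, and a common difference in silk stage or growth stays open, untested. The set itself holds 0 genes without 35S:P1 replicate 1 or any 1 empty-vector library, and P1's own level was not looked up.

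Genes changed alike by P1-rr in silk and pericarp, 442 of 21278, gathered at neighbouring identifiers, with 27 pairs next to each other against a mean of 9.14 and a highest of 20 in 10000 permutations. Chance placement is argued against by the permutation p = 0.0001, the smallest they can give, but other calls gathered too: 3 pairs against 0.621 for opposite directions (p = 0.02), 1001 against 881 for genes called in 1 tissue only and 7268 against 7085 for B73 against A632 (p = 0.0001 each). Stretches of DNA that differ between the stocks may be one source: in 15 of 500 windows of 100 identifier numbers, picked from these data for a share of 10% or more (permutations gave a mean of 2.77 and at most 8), 6 of 94 shared genes had 3 or fewer counts in 1 stock in both tissues, against 5 of 348 elsewhere (odds ratio 4.66, 95% interval 1.15 to 19.8, Fisher's exact test p = 0.015); only 1 of the 15 windows exceeds the highest share in 1000 permutations, 20.8%, but 8 lie in a single stretch, 28500 to 29399, with 59 of 437 tested genes shared (13.5%, against at most 6.99% in 9 windows in a row). Whether neighbouring genes respond to P1 cannot be told apart from this, since shared genes in the windows changed alike in blocked protoplasts in 11 of 89 against 52 of 325 (odds ratio 0.741, 95% interval 0.332 to 1.53, Fisher's exact test p = 0.51). Identifier numbers stand in for order here, no positions or sequences were used, and both stocks carry the same inbred name.

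P1 ChIP-seq peaks of F1 silk met P1 DAP-seq sites about as often, relative to shuffled peaks, as sites of other factors: 4.39 times, against 3.40 to 6.53. Peak density over stretches wider than 500 kb is argued against as the source of the P1 overlap by the ratio of 4.04 over peaks shifted within 500 kb. Density at a finer scale was not tested. The other lists kept ratios of 3.16 to 6.29 over shifted peaks, so the shifts cannot say why P1 resembles other factors. Sites shared by many factors cannot be told apart as a cause either. The interval of P1 lay above those of 5 of 10 other factors on all sites and of 8 on sites of 1 factor alone. A chromatin state that makes sites of all factors more often called cannot be decided on here, since its test repeats the pattern to be explained. The ratio on P1-only sites, 4.31 (3.98 to 4.66), lies in the range of the 10 other factors with 1000 or more sites of their own only through GBP20. That factor, assayed on methylated DNA, had 5.72 (4.17 to 7.85, from 38 peaks). The next was EREB122 with 3.59 (3.42 to 3.76), below the interval of P1, and the lowest DOF3 with 2.43. Of the shorter lists MYB40 had 4.80 (2.75 to 8.39), EREB7 3.51 and MYB100 1.43. In protoplasts P1 led with 12.96 against 7.92 among factors with 1000 or more sites of their own. No other biological explanation was tested, and the antibody's background in silk stays open.

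Whether other splits of the libraries call as many genes was counted for each remaining comparison, and in each 1 split, the real one, did. With 10 splits a share under 0.05 cannot be reached. The real count and the highest of the other splits were 35 and 0 in protoplasts, 3140 and 0 for P1 in silk, 2878 and 0 in pericarp, 13376 and 2 for the parents, 10733 and 1 for F1 against B73, and 11925 and 1 for F1 against A632. In protoplasts 4 splits part all 3 pairs, and with the block the real one called 1577 genes and the others 0. For F1 against the parental mean 1 of 100 splits, the real one, gave 10272 genes. The highest other, 9845, set the 3 A632 libraries against mixtures of B73 and F1, a split that follows the parental difference. These splits mix the libraries of F1 and both parents. They therefore cannot tell a departure of F1 from the parental mean apart from the difference between the parents.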
